A study of Homo sapiens with 6 samples.

How the data were processed

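Gene expression was measured by RNA sequencing in human pancreatic islets from 3 donors, as 1 untreated and 1 interferon-α (IFNα) library per donor, 6 libraries in all. Per the labels, islets were cultured for 24 h in medium with 5.5 mM glucose and 10% serum, and treated samples then received 2000 U/ml IFNα for 24 h. Untreated islets are recorded with 24 h of preculture and 0 h of treatment, without a total culture time. If they were not kept for the further 24 h, effects of culture time cannot be told apart from those of IFNα. Total RNA was extracted, and libraries were made with an Illumina TruSeq kit and sequenced as single reads, per the labels and the design text. The authors deposited raw read counts, 1 table per library, with 31537 entries that carry 20800 gene symbols. BWA and the human build hg19 are named per the submitters' processing notes, without a version or a role. The counting program, annotation, strand setting and read filters are not given in the sources used here. The annotation at hand was of another build, so no coordinates are printed.

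In the deposited counts, 6027 symbols had more than 1 entry. Among 4237 of them whose largest entry had at least 600 reads, the second entry held at least 80% of the reads of the first for 84.8% of symbols, with a median ratio of 0.971. This was read as transcripts that each count the reads they share, and the entry with the most reads over all libraries stood for its gene. Blank cells were read as 0, and 0 entries lacked a gene name. With 1 entry per gene the totals were 15059688, 12723504 and 14390574 reads in untreated libraries 1, 2 and 3. The totals were 16090460, 13808976 and 12418673 reads in the IFNα libraries of the same donors. XIST, Y-linked genes and genes whose level is largely set by common genotypes were left out of all tests, 103 symbols in all. Counts are uncertain for genes that share reads with near-identical copies or overlapping transcripts, such as INS with its readthrough transcript, HLA class I genes, and ribosomal protein genes with their pseudogenes.

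Groups and donor numbers were taken from the labels. The main test was the edgeR 4.0.16 quasi-likelihood F test with robust estimation (R 4.3.3), without a donor term, called unpaired here. It used TMM factors, the filterByExpr filter, which kept 17389 genes, and Benjamini-Hochberg adjustment at 0.05. Standard errors are the size of the log2 fold change divided by the square root of F. The paired fit added the donor as a block. The labels number the islets 1 to 3 in both groups and the design text names 3 donors, so libraries with the same number were taken as 1 donor; they deviated together from their group means, with correlations across genes of 0.858, 0.816 and 0.806. Libraries with different numbers had correlations of -0.611 to -0.133. Paired values are given where they change a call or a count. Libraries of a group differed far beyond sampling noise, with a chi-square per gene of 121 to 242, so each counted as its own sample.

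The gene lists, the designs, most alternatives and the rule for named genes were fixed before the data were examined. Of the lists, 30 had measured members and 1, of genes encoded in mitochondrial DNA, had none. Of 669 list entries 637 matched a symbol, 7 of them through an older symbol. Lists were tested with camera in limma 3.58.1 on log2 CPM, read counts scaled to library totals and TMM factors, with a prior count of 2 and a preset correlation between genes of 0.01. They were tested again with an estimated correlation and with fry. With an estimated correlation camera refers to the residual degrees of freedom, which are few here and fewest with the donor block. A list can then hardly pass, whatever its genes do. The rule for named genes took the 12 largest rises and the 12 largest falls past the threshold, if changed the same way in all 3 pairs and at 5 CPM or more in the higher group. It also took the 4 members of each list with the smallest p, and fixed genes, among them PNPT1, TET1, TET2, TET3, CTDSPL, CTDSP2, IFNAR1, IFNAR2, INS, GCG, SST, IAPP, HLA-B, HLA-C, CXCL10, MX1, PDX1 and MAFA. Some genes that this rule took are not reported here. With fewer than 5 falls in the unpaired test, the rule took the falls from the paired fit. Other genes named were chosen after their values were seen. Hormone shares and mean log2 CPM of cell type lists were compared by two-sided exact permutation tests, in which 3 libraries against 3 allow no p below 0.1 and 3 pairs none below 0.25.

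The alternatives were other scaling factors, filters and thresholds, DESeq2 1.42.0, limma-voom, and each library and each donor left out. A correction for GC content and transcript length used GENCODE 29, which covered 96.2% of tested genes. Other ways to combine the entries of a gene, further settings of the paired fit and a fit without robust estimation were added after the data were seen. The ribosomal protein genes were chosen by symbol after the data were seen, and the set was widened from 80 to 84 genes after the values of the first set were known.

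The tests were tested on simulated data for the IFNα comparison, with counts drawn from the real donor means and library sizes and 200 changed genes, in 5 runs per setting. With gene-specific spread (17228 to 17240 genes), 4.35% to 14.5% of the paired edgeR calls were false, and 9.15% over the 5 runs. Of these 100 false calls, 64 were among the 2% of genes with the most excess spread. The paired fit recovered 98.2% of 2-fold, 99.7% of 4-fold and 100% of 16-fold changes. With spread on a smooth trend (17194 to 17244 genes), 2.44% to 5.66% of its calls were false. The paired fit can therefore exceed its nominal share of false calls. In the runs with gene-specific spread, 2.02% to 5.74% of the calls of DESeq2 with the donor block were false. The unpaired edgeR test made 0 false calls there, among 423 calls, and recovered 0.299% of 2-fold, 42.4% of 4-fold and 84.8% of 16-fold changes. Camera called 0 of 30 lists of unchanged genes in either design. Counts were simulated gene by gene, so this cannot show how often camera calls unchanged lists whose genes vary together. In the real lists the estimated correlation between genes was -0.0263 to 0.941 unpaired and -0.0581 to 0.743 with the donor block.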

Results

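RNA of whole islets, the endocrine micro-organs of the pancreas, was measured in 3 untreated libraries and in 3 libraries from islets exposed to IFNα, an antiviral cytokine. Islet preparations also hold acinar, duct, vascular, stromal and immune cells. The libraries held 12418673 to 16090460 counted reads. The comparison addresses how islets respond to IFNα and, from the title of the series, how PNPT1 and TET2 behave.

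IFNα raised a broad set of antiviral genes. ISG15, a ubiquitin-like modifier, rose from 13.5 ± 3.59 to 2449.8 ± 289 CPM (read counts scaled to library totals; SD, n = 3 per group), a log2 fold change of 7.50 ± 0.48 (SE; edgeR adjusted p = 0.00503), and was higher in 3 of 3 pairs. IFIT1 (6.92 ± 0.69), IFIT2 (6.81 ± 0.84), IFI44L (6.81 ± 0.91) and IFIT3 (6.61 ± 0.50) followed. The GTPase MX2 rose by 6.41 ± 0.27, and the oligoadenylate synthetase family members OASL and OAS2 by 6.29 ± 0.59 and 6.16 ± 0.39. IFITM1, OAS1, MX1 and LAMP3 rose by 6.08, 5.96, 5.86 and 5.72 on the log2 scale, though the paired call of LAMP3 was lost without donor 1 (5.51, adjusted p = 0.14). In the unpaired edgeR test 82 of 17389 genes rose and 0 fell. At an unadjusted p under 0.05 there were 510 higher and 93 lower genes. DESeq2 called 227 higher and 6 lower genes, and limma-voom 83 and 0. Without untreated library 1, 2 or 3 the edgeR test called 22, 0 and 30 higher genes, and without IFNα library 1, 2 or 3 it called 59, 41 and 52.

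With the donor as a block, 799 genes rose and 427 fell in the edgeR test, and all 82 were among the 799. Of these, 338 rose and 30 fell by more than 2-fold. CERK, which encodes ceramide kinase, fell from 248.5 ± 40.03 to 77.5 ± 16.3 CPM (SD, n = 3), a paired log2 change of -1.69 ± 0.11 (adjusted p = 8.59e-08), and was lower in 3 of 3 pairs. ACAN (-1.69 ± 0.29), the matrix protease MMP9 (-1.59 ± 0.28) and NT5DC2 (-1.50 ± 0.12) fell too. REG4, CMTM4, FGG, TNFRSF10D, LOC389332, CNTN1, SFRP5 and SERPINA5 had paired changes of -1.40, -1.34, -1.32, -1.31, -1.30, -1.29, -1.24 and -1.16. None of these 12 passed the unpaired test, where CMTM4 (adjusted p = 0.0555) and CERK (adjusted p = 0.0634) came nearest. The share of higher genes, 65.2%, was 51.3% with upper-quartile factors (706 higher, 669 lower) and 55.4% with library totals alone (926 and 746). In simulations 4.35% to 14.5% of the calls of this fit were false, and without donor 1, 2 or 3 it called 607, 433 and 1261 higher and 247, 135 and 802 lower genes. Calls were lost for TNFRSF10D (-1.46, adjusted p = 0.0677) and SERPINA5 (-1.16, adjusted p = 0.0755) without donor 1, ACAN (-0.80, adjusted p = 0.41) without donor 2 and REG4 (-0.40, adjusted p = 0.56) without donor 3.

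**Figure D1:**
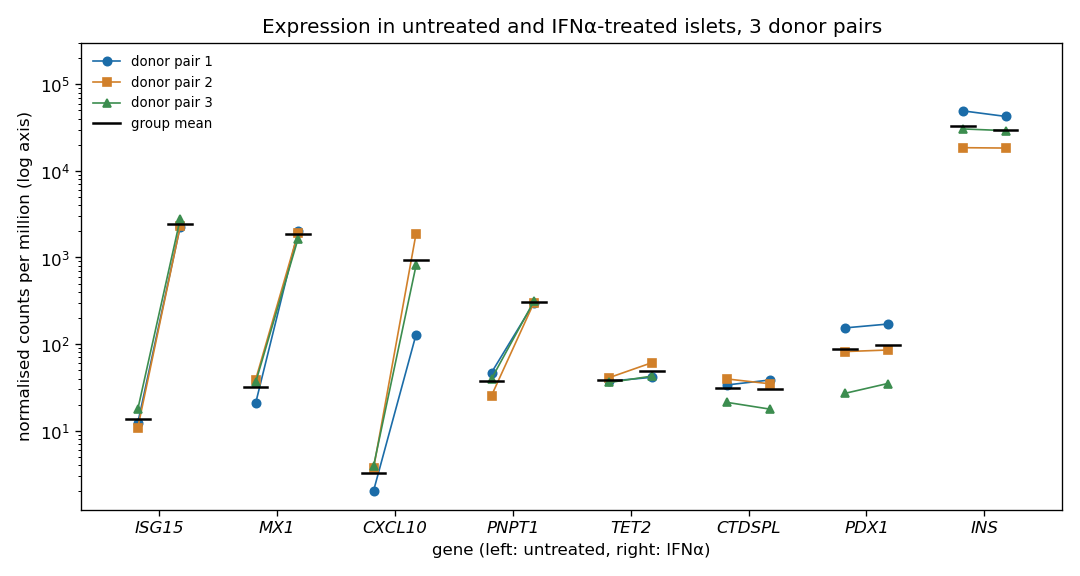
Normalised read counts (CPM, log axis) of 8 genes in untreated (left) and IFNα-treated (right) islets; each symbol is 1 library, lines join the libraries of a donor, and black bars are means of 3 libraries. ISG15, MX1, CXCL10 and PNPT1 lie higher in each treated library than in each untreated one, while the differences within pairs are 0.15 to 0.57 log2 units for TET2 and -0.21 to -0.014 for INS.

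Antiviral effectors moved most among the lists. Of 58 measured members, 41 rose, 0 fell and 17 did not pass in the unpaired test, and 56 rose when adjusted over the list alone. SP110 (3.67 ± 0.20) and BST2 (5.38 ± 0.34), which tethers budding virus, were among them. In the paired fit 57 rose, also adjusted over the list alone, the exception being APOL1 at 2.22 ± 0.76 (adjusted p = 0.334), which passed without donor 1 (1.52, adjusted p = 5.88e-05) and with DESeq2 and the block. The list test camera gave adjusted p = 1.7e-187, and adjusted p = 0.0157 with an estimated correlation. With the donor block it was adjusted p = 1.74e-92, and adjusted p = 0.119 with an estimated correlation.

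Of 8 guanylate-binding protein and MX genes, MX1 and MX2 rose and 6 did not pass, and 5 rose adjusted over the list alone. With the donor block 7 rose, also adjusted over the list alone, among them GBP1 (3.66 ± 0.21) and GBP5 (3.31 ± 0.23). The list had a camera adjusted p = 1.19e-18, and adjusted p = 0.124 with an estimated correlation. Of 18 nucleic acid sensors and their partners 4 rose and 14 did not pass, and 11 rose adjusted over the list alone. DDX58, which encodes the RNA sensor RIG-I, rose by 4.92 ± 0.43, IFIH1 by 3.81 ± 0.32, DHX58 by 3.45 ± 0.26 and the nucleotide hydrolase SAMHD1 by 3.35 ± 0.24. Paired, 14 rose, also adjusted over the list alone. For the sensors camera gave adjusted p = 6.69e-29, and adjusted p = 0.0682 with an estimated correlation.

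In the interferon signalling list 5 of 18 members rose and 13 did not pass, and 6 rose adjusted over the list alone. STAT2 rose by 2.17 ± 0.26, IRF7 by 3.48 ± 0.30 and the negative regulator USP18 by 4.86 ± 0.47. The receptor chains IFNAR1 (-0.20 ± 0.26) and IFNAR2 (-0.14 ± 0.41) did not pass. Paired, 9 members rose, also adjusted over the list alone. The signalling list had a camera adjusted p = 1.9e-13, and adjusted p = 0.0682 with an estimated correlation.

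Genes of class I antigen presentation included 2 rises among 21 members, NLRC5, a transactivator of these genes (2.54 ± 0.19), and the proteasome activator PSME2 (1.73 ± 0.23). The other 19 did not pass, and 11 rose adjusted over the list alone. Paired, 16 rose, also adjusted over the list alone. HLA-B and HLA-C, whose reads may be shared between near-identical copies, had paired changes of 1.47 ± 0.12 and 1.57 ± 0.12, and B2M, their light chain, 1.26 ± 0.16. Class I genes had a camera adjusted p = 1.62e-25, and adjusted p = 0.0682 with an estimated correlation. Of 12 class II genes 0 passed unpaired, also adjusted over the list alone, and 3 rose in the paired fit, also adjusted over the list alone. These were CTSS (1.60 ± 0.12), CD74 (1.04 ± 0.14) and HLA-DPB1 (0.55 ± 0.14). Camera gave adjusted p = 0.466 unpaired, adjusted p = 0.000639 without untreated library 2, and adjusted p = 0.0247 paired, where it was adjusted p = 0.419 with an estimated correlation. HLA-DPB1 did not pass without donor 1 (0.55, adjusted p = 0.125) or donor 2 (0.52, adjusted p = 0.287).

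**Figure D2:**
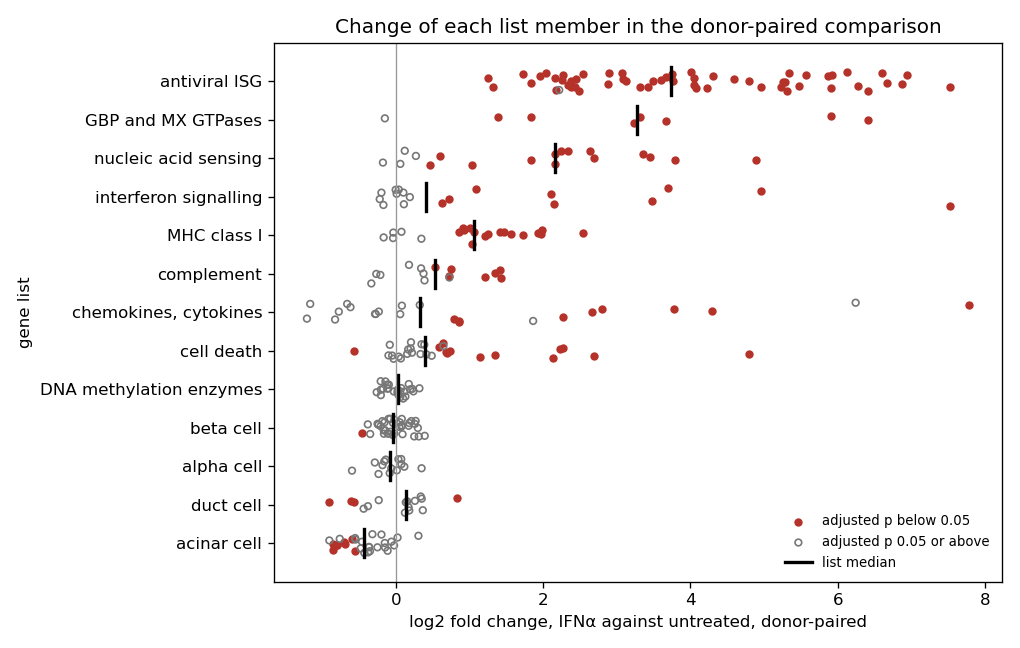
Paired log2 fold change of each member of 13 gene lists; points are genes, filled where the adjusted p was below 0.05 and open otherwise, and black bars are list medians. The median of the antiviral list lies at 3.74, that of the beta cell list at -0.038 and that of the acinar list at -0.43.

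Among chemokines and cytokines CXCL10, which attracts T cells, went from 3.21 ± 1.03 to 939.5 ± 884 CPM (SD, n = 3), a change of 8.19 ± 1.15 that did not pass unpaired (adjusted p = 0.051). It rose in the paired fit (7.78 ± 0.77, adjusted p = 0.0393), though not without donor 3 (7.97, adjusted p = 0.382). CX3CL1 rose as well (2.66 ± 0.12). CXCL11, at 6.24 ± 0.98, did not pass paired (adjusted p = 0.13) but did without donor 1 (7.01, adjusted p = 7.88e-10) and with DESeq2 and the block. Of 23 members 0 passed unpaired and 4 rose adjusted over the list alone, and in the paired fit 9 rose, or 11 adjusted over the list alone. The chemokine list had a camera adjusted p = 1.24e-05, adjusted p = 0.674 with an estimated correlation, and adjusted p = 0.249 without untreated library 1.

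Of 15 complement genes 0 passed unpaired, also adjusted over the list alone, while 7 rose in the paired fit, or 10 adjusted over the list alone. They included the proteases C1S (1.42 ± 0.12) and C1R (1.43 ± 0.13) and their inhibitor SERPING1 (1.21 ± 0.14). Complement genes had a camera adjusted p = 0.0379, and adjusted p = 0.428 with an estimated correlation. This call was lost without untreated library 1 or 3 (adjusted p = 0.158 and 0.0813), without IFNα library 2 or 3 (adjusted p = 0.21 and 0.0685) and without donor 3 (adjusted p = 0.18). Of 15 checkpoint genes 2 rose and 13 did not pass, and 6 rose adjusted over the list alone. CD274, which encodes PD-L1, rose by 2.33 ± 0.22 and IL18BP by 3.16 ± 0.42. Paired, 7 rose, also adjusted over the list alone. IDO1, at 2.95 ± 0.95, did not pass (adjusted p = 0.315), but did without donor 2 (1.96, adjusted p = 1.68e-06) and with DESeq2 and the block. Checkpoint genes had a camera adjusted p = 3.44e-09, and adjusted p = 0.211 with an estimated correlation.

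Of 30 cell death genes XAF1 rose (4.77 ± 0.41) and 29 did not pass, and 4 rose adjusted over the list alone. With the donor block 12 rose and BAD fell (-0.57 ± 0.13), or 16 and 1 adjusted over the list alone. The necroptosis effector MLKL rose by 2.14 ± 0.16, GSDMD by 1.34 ± 0.14, the death ligand TNFSF10 by 2.27 ± 0.13 and CASP1 by 2.22 ± 0.24. Cell death genes had a camera adjusted p = 1.85e-09, and adjusted p = 0.333 with an estimated correlation. Of 25 candidate genes for type 1 diabetes IFIH1 rose and 24 did not pass, with 1 adjusted over the list alone. Paired, 4 rose, among them IFIH1, GSDMB (1.25) and SH2B3 (0.43), and CTSH fell (-0.56), or 5 and 1 adjusted over the list alone. The candidate list had a camera adjusted p = 0.00439, adjusted p = 0.198 with an estimated correlation, and adjusted p = 0.112 without IFNα library 2. Without donor 1 the paired calls of BAD (adjusted p = 0.137) and SH2B3 (adjusted p = 0.22) were lost, and without donor 2 those of CTSH (adjusted p = 0.0522) and SH2B3 (adjusted p = 0.304).

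PNPT1 encodes polynucleotide phosphorylase, a mitochondrial ribonuclease. It rose from 37.3 ± 10.9 to 304.5 ± 7.64 CPM (SD, n = 3), a log2 fold change of 3.03 ± 0.28 (edgeR adjusted p = 0.0104), and was higher in 3 of 3 pairs. The paired value was 3.07 ± 0.16 (adjusted p = 6.43e-08). TET2, a methylcytosine dioxygenase, had 38.1 ± 2.62 CPM untreated and 48.3 ± 10.97 with IFNα, a change of 0.34 ± 0.21 that did not pass (edgeR adjusted p = 1.00). Its paired value was 0.32 ± 0.12, higher in 3 of 3 pairs, which did not pass (edgeR adjusted p = 0.138, DESeq2 adjusted p = 0.356). It passed without donor 3 (0.37, edgeR adjusted p = 0.043), where its SE was 0.13, no smaller than with all donors. That pass therefore did not come from a tighter estimate. TET1 (0.20 ± 0.27) and TET3 (-0.23 ± 0.25) did not pass in either fit. Nor did CTDSPL (-0.053 ± 0.37) and CTDSP2 (-0.018 ± 0.25), which host the miR-26a precursors in introns. Each taken alone, the unadjusted edgeR p was 0.154 unpaired and 0.0175 paired for TET2, and 0.889 and 0.566 for CTDSPL. Mature miR-26a was not analysed here. In the paired fit PNPT1 passed without donor 1, 2 or 3 (3.26, 2.83 and 3.11, adjusted p = 1.51e-08, 9.63e-11 and 9.63e-92). The unpaired PNPT1 call was lost without untreated library 1, 2 or 3 (adjusted p = 0.0502, 0.0613 and 0.0793) and without both libraries of donor 1, 2 or 3 (adjusted p = 0.108, 0.258 and 0.318), at log2 changes of 2.81 to 3.23.

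In the list around this axis PNPT1 rose and 7 of 8 members did not pass in either fit, with the same count adjusted over the list alone, and camera gave adjusted p = 0.0541, adjusted p = 0.293 with an estimated correlation and adjusted p = 0.206 paired. The list test passed without a filter on low counts (adjusted p = 0.035) and without IFNα library 1, untreated library 2 or 3, or donor 2 (adjusted p = 0.0385, 0.0124, 0.0475 and 0.0476). Of 25 enzymes of DNA methylation and demethylation 0 passed in either fit, also adjusted over the list alone, with paired changes of -0.26 to 0.32. At an unadjusted p under 0.05 it was 0 of them unpaired and 1 higher and 1 lower paired, and DESeq2 and limma-voom called 0 in either design. Of 15 genes of mitochondrial RNA turnover PNPT1 rose and 14 did not pass, also adjusted over the list alone. Paired, PNPT1 rose and ENDOG fell (-0.61 ± 0.16), also adjusted over the list alone. ENDOG did not pass without donor 1 (-0.60, adjusted p = 0.146) or donor 2 (-0.54, adjusted p = 0.26).

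Genes of the endocrine cells showed few changes past the threshold. INS, GCG, SST, PPY and IAPP together took 5.37 ± 3.52% of reads untreated and 4.56 ± 2.38% with IFNα (SD, n = 3), a difference of -0.81 points that was lower in 2 of 3 pairs (exact permutation p = 0.6, within pairs 0.5). Without donor 1, 2 or 3 it was -0.15, -1.04 and -1.24 points, and the median over pairs was -0.35. INS (-0.13 ± 0.78), GCG (-0.43 ± 1.07), SST (0.15 ± 0.63) and IAPP (-0.80 ± 1.16) did not pass in either fit. IAPP passed in the paired fit without donor 3 (-0.51, adjusted p = 0.00965), where p-values rest mostly on the spread shared across genes. Of 36 beta cell genes 0 passed unpaired, also adjusted over the list alone, and PDX1 and MAFA, transcription factors of these cells, had paired changes of 0.18 ± 0.11 and -0.036 ± 0.13. UCN3, a hormone gene of mature beta cells, went from 56.7 ± 19.4 to 40.8 ± 11.01 CPM and fell in the paired fit (-0.45 ± 0.12, adjusted p = 0.0278), lower in 3 of 3 pairs, with 0 genes adjusted over the list alone. None of 14 alpha cell genes or 25 secretory granule genes passed in either fit, also adjusted over the list alone, and DESeq2 and limma-voom called 0. At an unadjusted p under 0.05 there were 0 unpaired, and paired 1 higher alpha cell gene and 3 lower granule genes. Of 12 genes of delta, PP and epsilon cells 0 passed unpaired, also adjusted over the list alone, and BCHE fell in the paired fit (-0.70 ± 0.20), or 1 higher and 1 lower adjusted over the list alone. Camera gave no call for the beta cell list (adjusted p = 0.852). It placed the list higher without untreated library 1 (adjusted p = 0.00684) and lower without IFNα library 1 or untreated library 3 (adjusted p = 0.00229 and 0.00145). These unpaired fits hold 1 donor in 1 group only, so they cannot part that donor's own level from an effect of IFNα. UCN3 did not pass without donor 1 (-0.44, adjusted p = 0.12) or donor 2 (-0.37, adjusted p = 0.394), nor did BCHE (adjusted p = 0.127 and 0.43).

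Among the other cell types, acinar genes moved most by the mean log2 CPM of each list. With the median level over members in each library in place of the mean, the duct value was larger (-0.42, against -0.34 for the acinar list). That value follows the members of middle abundance. The median of the paired changes was 0.15 for duct genes and -0.43 for acinar genes. Paired, 8 of 29 acinar genes fell, 0 rose and 21 did not pass, or 14 lower and 1 higher adjusted over the list alone. CELA2A (-0.80 ± 0.14), CELA2B (-0.84 ± 0.17), PNLIPRP1 (-0.71 ± 0.13) and PRSS1 (-0.55 ± 0.15), genes of digestive enzymes and a lipase relative, were among them. Unpaired, 0 passed, also adjusted over the list alone. Camera gave adjusted p = 0.256 unpaired and adjusted p = 3.61e-06 paired, and the paired value was adjusted p = 0.653 with an estimated correlation. Unpaired, camera placed the list lower without untreated library 1 or 2 or IFNα library 3 (adjusted p = 0.00154, 0.0039 and 3.15e-07). It placed the list higher without untreated library 3 (adjusted p = 0.00512). There too the donor of the left-out library stayed in 1 group only, so its own level entered the contrast. The acinar mean differed by -0.39 ± 0.32 log2 units between IFNα and untreated libraries (SD over 3 pairs; exact permutation p = 0.6, within pairs 0.25, the smallest that 3 pairs can give), against a range of 4.05 between untreated donors. Means of the cell type lists gave exact permutation p from 0.6 to 1 and within pairs from 0.25 to 1, and 1 after adjustment in both cases. CELA2B did not pass without donor 3 (-0.49, adjusted p = 0.274) and PRSS1 not without donor 1 (-0.40, adjusted p = 0.295).

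Of 16 duct genes CFTR (-0.91 ± 0.13), SLC4A4 (-0.56 ± 0.12) and TFF1 (-0.61 ± 0.15) fell and MMP7 rose (0.84 ± 0.15) in the paired fit, or 5 and 3 adjusted over the list alone. Of 15 endothelial genes FLT1 (-0.43 ± 0.12) and PECAM1 (-0.51 ± 0.14) fell, or 3 lower and 1 higher adjusted over the list alone. Of 18 leukocyte genes CD68 (1.73 ± 0.23) and CD163 (0.84 ± 0.21) rose and CD14 fell (-0.57 ± 0.15), also adjusted over the list alone. Of 16 stellate and mesenchymal genes RGS5 fell (-0.44 ± 0.12), with 0 adjusted over the list alone. Unpaired, 0 genes of these lists passed, and 1 leukocyte gene rose adjusted over the list alone. Without donor 1 the calls of TFF1 (adjusted p = 0.0858), PECAM1 (0.217), CD163 (0.311), FLT1 (0.0645), CD14 (0.0689) and RGS5 (0.322) were lost. Without donor 2 those of SLC4A4 (adjusted p = 0.144), TFF1 (0.25), FLT1 (0.271), CD14 (0.0526) and RGS5 (0.182) were lost, and without donor 3 those of FLT1 (0.0576) and CD14 (0.0563).

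Camera placed 41 nuclear genes of the respiratory chain lower (adjusted p = 0.0069, list median -0.13), and adjusted p = 0.674 with an estimated correlation. The call was lost without untreated library 1 (adjusted p = 0.249), IFNα library 1 or 2 (adjusted p = 0.12 and 0.159) or donor 1 or 2 (adjusted p = 0.63 and 0.0624). Paired, 36 of 41 lay below 0 (median -0.14, adjusted p = 0.0158, and adjusted p = 0.999 with an estimated correlation). None of them passed unpaired, also adjusted over the list alone, and NDUFA9 rose in the paired fit (0.67 ± 0.12), also adjusted over the list alone. Of 26 genes of the unfolded protein response CHAC1 rose in the paired fit (0.95 ± 0.18), also adjusted over the list alone. Of 19 proliferation genes BUB1 (1.07 ± 0.17) and BIRC5 (1.70 ± 0.33) rose, and of 17 NF-κB genes CFLAR (0.98), BIRC3 (0.68) and TRAF1 (0.44), in both cases also adjusted over the list alone. Of 16 hypoxia genes ANKRD37 rose (0.45), or 1 higher and 2 lower adjusted over the list alone. Of 20 immediate early and stress genes KLF6 rose (0.55) and IER3 fell (-0.70), or 1 and 2 adjusted over the list alone. Of 14 housekeeping genes TFRC (-0.69), RPLP0 (-0.63) and RPL13A (-0.50) fell, or 5 adjusted over the list alone. Unpaired, 0 genes of these lists passed, also adjusted over the list alone. Over the 20 lists without an unpaired edgeR call, with 401 genes, 14 genes were higher and 0 lower at an unadjusted p under 0.05. DESeq2 called 5 higher and 0 lower of them, and limma-voom 1 and 0.

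Without donor 1 the paired calls of ANKRD37 (adjusted p = 0.0864), TRAF1 (0.209), KLF6 (0.0537), IER3 (0.193), RPLP0 (0.0916) and RPL13A (0.158) were lost. Without donor 2 these were lost too (adjusted p = 0.613, 0.441, 0.161, 0.079, 0.132 and 0.246), as were NDUFA9 (0.0801), BIRC3 (0.0996) and TFRC (0.177). List medians and means of paired changes differed in sign for unfolded protein response (-0.076 and 0.026), duct (0.15 and -0.012), stellate (0.029 and -0.01) and proliferation genes (-0.033 and 0.068). Camera leaned higher for the unfolded protein response, duct and stellate lists and lower for proliferation and for mitochondrial RNA turnover (median 0.01, mean 0.14), with adjusted p of 0.966 to 0.997. Paired calls of UCN3, HLA-DPB1, PECAM1, CD163, TFF1, FLT1, CD14, ENDOG, BCHE, ANKRD37, TRAF1, RGS5, IER3 and SH2B3 were not made by DESeq2 with the block. After the GC and length correction those of UCN3, PECAM1, BAD, PRSS1, ENDOG, BCHE and ANKRD37 were lost.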

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

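Sums of entries, every entry tested, cell type means without a donor, fits without robust estimation, and the paired fit with other scaling, filters, voom or a threshold of 0.01 were chosen only after the results were seen. Against 82 higher and 0 lower genes, the donor pairing (block) gave 799 and 427, DESeq2 227 and 6, DESeq2 with the block 597 and 263, the block with GC and length correction 807 and 496, and a threshold of 0.01 gave 27 higher. Lower genes numbered 1 with RLE factors, with totals without hormone genes and without a filter, and 2 with upper-quartile factors, with sums of entries and with every entry tested. Leaving out a library or donor gave 0 to 59 higher genes, with 0 without untreated library 2 and without any donor, where fewer samples remain. The paired counts became 82 and 0 without the block, 490 and 120 at a threshold of 0.01, and 433 to 1261 higher and 135 to 802 lower without a donor. Lower genes in the paired fit numbered 669 with upper-quartile factors, 746 with library totals and 263 with DESeq2. Of the list tests, 10 higher and 1 lower, estimated correlation left 1 and 0 and fry 5 and 0. With the block, fry gave 8 and 1 and estimated correlation 0 and 0. With few residual degrees of freedom hardly any list could pass the latter. The block gave 2 lower lists, and leaving out a library or donor 0 to 6. The causes of these differences were not tested, though a left-out library leaves its donor in 1 group of the unpaired test. Fits with equally few samples also differed in their counts. Among the genes named and the camera tests with the preset correlation, the block changed no other call than those given.

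PNPT1 lay between 2.81 and 3.23 with a library or donor left out, and its direction held under each alternative. Genes without a call changed sign over these ranges: TET1 -0.020 to 0.42, CTDSPL -0.27 to 0.22, CTDSP2 -0.18 to 0.12, IFNAR2 -0.55 to 0.13, INS -0.47 to 0.29, IAPP -2.04 to 1.22, PDX1 -0.54 to 0.84, MAFA -0.79 to 0.81, GCG -1.27 to 0.81 and SST -0.22 to 0.54. Where 1 library was left out its donor stayed in 1 group only, so these ranges also hold differences between donors. With the block and the GC and length correction INS was at 0.096 and MAFA at 0.050. Of 46 genes followed in the unpaired test 30 lost their call without untreated library 2, 16 without untreated library 1 and 14 without untreated library 3, and 6, 8 and 6 without IFNα library 1, 2 or 3. Of 93 genes followed in the paired fit 26, 27 and 4 lost their call without donor 1, 2 or 3, 86 without the block and 14 with DESeq2. Of these 93, 24 changed sign in the unpaired test with 1 library left out. The hormone share and the means of cell type lists moved by less than the SD between libraries of a group in each alternative. That SD holds the differences between donors and is wider than the effects themselves. For the acinar list it was 2.25 untreated, against a difference of -0.39, so this bound could hardly be passed. With the median level over members in each library in place of the mean, the duct value went from -0.017 to -0.42. That of delta, PP and epsilon cells went from -0.031 to 0.13. Both moves were larger than their SD over pairs (0.046 and 0.080). Such a value follows the members of middle abundance, and the median of the paired changes of duct genes was 0.15. TET1, at 1.69 ± 0.41 CPM untreated, was among the lowest genes named, and a limit set by depth was not tested there.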

Other observations

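The tests of gene families, of the GC and length correction for ribosomal protein genes, of the duct genes without a donor, of a change shared by acinar genes and of the spread of genes matched to them were chosen only after the result was seen. Families were genes that share the letters before the first digit of the symbol, at least 5 tested, without HLA and generic prefixes such as ZNF, LOC or FAM. A one-sided Fisher's exact test of the paired calls over 529 families, with Benjamini-Hochberg adjustment, called 12 families for higher and 3 for lower genes. All 6 genes with BTN and a digit in the symbol, of the butyrophilin family of membrane proteins, rose (adjusted p = 3.7e-06), with BTN3A3 at 2.01 ± 0.18 (SE) and BTN3A1 at 1.48 ± 0.17. Of 13 PARP genes 7 rose (adjusted p = 7.5e-05), including the ADP-ribosyltransferase gene PARP14 (3.50 ± 0.13). Of 62 TRIM genes 13 rose (adjusted p = 0.000287), among them TRIM22 (3.76 ± 0.13). Of 8 APOBEC genes, cytidine deaminases, 4 rose (adjusted p = 0.0157), such as APOBEC3G (2.69 ± 0.14).

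Of 11 histone genes with HIST symbols 6 rose (adjusted p = 0.000287), with HIST2H2BE at 1.46 ± 0.12 and HIST1H2BK at 0.87 ± 0.13. The lower families held symbols starting with RPL (19 of 69 lower, adjusted p = 1.38e-12) and RPS (12 of 46, adjusted p = 1.99e-07), which are mostly ribosomal protein genes and their pseudogenes. The RPL calls included RPL13A with RPL13AP20, RPL13AP3, RPL13AP5 and RPL13AP6, which may share reads, while Fisher's exact test takes genes as independent. RPS6KC1, a kinase-related gene with an RPS symbol, rose (0.58 ± 0.12) but did not pass without donor 2 (adjusted p = 0.201). Of 6 SERPINA genes, members of the serpin family, 3 fell (adjusted p = 0.0491). Among them was SERPINA6 (-1.03 ± 0.21), which did not pass without donor 2 (adjusted p = 0.19).

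Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real one, which was the real one itself, with 82 genes against 0 as the highest other; a share under 0.05 is not possible with 10 splits. Of the 4 splits that part all 3 pairs, 1 gave as many genes in the paired fit, again the real one, with 1226 against 0; a share under 0.05 is not possible with 4 splits.

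Ribosomal protein genes were lower in the paired fit, where 83 of 84 lay below 0, 27 passed and the median was -0.35. Its SE from resampling these genes was 0.022, which does not measure the spread over donors. The median differences were -0.51, -0.32 and -0.24 in pairs 1, 2 and 3. Without donor 1, 2 or 3, 4, 1 and 57 genes passed, at medians of -0.28, -0.37 and -0.41. Under TMM, RLE and upper-quartile factors and library totals the paired median was -0.35, -0.35, -0.40 and -0.37, and 27, 26, 39 and 44 genes passed. Relative to the median of all genes it was -0.33 in each. Scaling factors shift all genes nearly alike, so that last value could hardly differ and is no test of scaling. Unpaired, 0 passed and the median was -0.31. It was -0.47, -0.48 and 0.13 without untreated library 1, 2 or 3 and -0.092, -0.12 and -0.90 without IFNα library 1, 2 or 3. These values without 1 library also hold differences between donors. A GC and length trend as the whole cause is argued against by a median of -0.34 after its correction, a loss of all abundant transcripts by a lowest median of -0.15 over 1000 random lists matched on CPM, and a lower acinar content by a ribosomal median of -0.32 in the pair where acinar genes changed least. Reads shared with pseudogenes were not tested and stay open, so a lower level of these transcripts under IFNα may be proposed only as a hypothesis.

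CFTR, a chloride channel gene, SLC4A4, a bicarbonate transporter gene, and TFF1 were lower and MMP7 was higher in 3 of 3 pairs, though TFF1 did not pass without donor 1 (-0.56, adjusted p = 0.0858) or donor 2 (-0.57, adjusted p = 0.25), nor SLC4A4 without donor 2 (-0.52, adjusted p = 0.144). A loss of duct cells is argued against by the keratins KRT7, KRT18 and KRT19, whose median paired change was 0.17. KRT19 was at 0.26 ± 0.13 and passed without donor 3 (0.41, adjusted p = 0.024). The argument holds only if these keratins do not themselves respond to IFNα, which was not tested. Over the 16 duct genes, 8 were higher and 6 lower in all 3 pairs. In the paired fits without donor 1, 2 or 3 each of the 4 genes kept its direction, with a change of at least 2.54 SE. The genes were chosen by their paired calls, and each had moved 1 way in 3 of 3 pairs. A turn in direction was thus hardly possible, and nothing is concluded from these fits on a single deciding donor. Expression that changes within duct cells may be proposed only as a hypothesis, and other cell sources of these transcripts were not tested.

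Acinar genes had a median paired change of -0.43. Their median differences were -0.65, -0.0319 and -0.65 in pairs 1, 2 and 3, so a fall shared by donors and a fall set by some donors cannot be told apart with 3 pairs. A lower share of acinar cells alone would lower these genes alike within a pair. Over 25 genes at 50 CPM or more the SD of their differences was 0.469 ± 0.052, 0.247 ± 0.038 and 0.410 ± 0.041 (SE over genes) in pairs 1, 2 and 3. The bound set in advance was 0.3 in every pair, and pairs 1 and 3 exceeded it. Of 1000 lists of other genes matched on CPM and without a paired call, 7.5%, 48.9% and 12.5% had an SD as high. Their median SD of 0.288, 0.247 and 0.325 lay near the bound. Among matched lists that kept called genes, 71.2%, 97% and 81.2% had an SD as high. The SD therefore cannot decide on a lower share alone. The paired changes lay further apart than their SE give (Cochran's Q of 111, and of 66.5, 89.5 and 117 without donor 1, 2 or 3, where a shared change gives about 24). This argues against 1 change shared by all 25 genes, but Q was not computed for other genes. A lower share together with changed expression may be proposed only as a hypothesis and was not tested.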
